A study of Drosophila melanogaster with 2 samples.

How the data were processed

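The series measured the binding of Lim3, a LIM-homeodomain transcription factor, along the genome of whole Drosophila melanogaster embryos of 8 to 24 h. That age comes from the source label, and a separate age label, whose value differs and is no plausible embryo age, was not used. The flies carried Lim3 fused to eGFP, and chromatin sheared by sonication was precipitated with an antibody against GFP, per the labels. The labels give 1 group with 2 biological replicates, so no comparison between conditions exists in the design. The replicates were compared with each other, and the thresholded peaks with the ranked peaks that overlapped no thresholded peak.

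The files used were peak lists in coordinates of the dm6 assembly, per the labels. Each replicate had a ranked list and a thresholded list, and 2 pairs of such lists came from both libraries together. Of the lists from both libraries, the thresholded list with more peaks is called the larger list, and the authors named the other one conservative. The aligner, the peak caller and their versions are not given in the sources used here. The alignments behind each list are named in the deposited descriptions, which also name 1 further input file per list that was not analysed here. No control library was analysed here. The signal of each peak is the authors' own value from their peak caller, on a scale not given in the sources used here, and it served only to rank or describe peaks within 1 list. The score of each deposited peak is scaled from its irreproducible discovery rate (IDR) to at most 1000, and it rises as the IDR falls. The ranked lists hold the authors' −log10 of the IDR as well. The deposited thresholded lists held only ranked peaks with an IDR of 0.01 or less. They also lacked some ranked peaks past that limit, which numbered 124 for the larger list, 47 for the conservative list, 160 for replicate 1 and 22 for replicate 2. Every scaffold peak past the limit that lay outside the scaffolds assigned to X was among the missing peaks. The reason for the absence of the missing peaks is not given in the sources used here. Read counts and depth per library are unknown, so the precision given below is that of counted peaks.

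Peak ends lay within the chromosome lengths of the reference used, release 6 of the fly genome, the assembly that dm6 denotes. Scaffold names differed between the deposited lists and the annotation, so peaks outside the 7 arms (X, Y, 2L, 2R, 3L, 3R and 4) were counted and left out of annotation and sequence work. Summits were placed in classes by priority: promoter (within 500 bp of the start of a transcript, TSS), 5' UTR, CDS, 3' UTR, non-coding exon, intron and intergenic. Promoters took the starts of all transcripts except those of transposons. Each peak was assigned to the protein-coding gene with the nearest TSS, which does not show that the gene is regulated by the site. Peaks in 1 list can overlap each other and were not merged, so counts of peaks per gene include such neighbours.

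The background was the set of ranked peaks from both libraries that overlapped no thresholded peak of the list tested nor of the larger list. It could therefore include ranked peaks past the IDR limit that the thresholded lists lacked. For sequence tests, up to 5 background windows per peak were drawn with a fixed seed, matched on GC content in bins of 2 percentage points and on promoter class. A 200 bp window centred on the summit was searched for a word on either strand. Fisher's exact test, two-sided, compared the shares, and the Benjamini-Hochberg method adjusted p over 18 panel motifs, 2080 hexamers, 7 position classes, 8 chromosome classes or 17 gene lists. The panel included 3 rearrangements of the letters of TAATTA (ATTAAT, TTATAA and AATATT) as controls for composition. Shares carry Wilson 95% intervals, and odds ratios carry Wald 95% intervals with 0.5 added to each cell. The odds ratios between replicates within GC bins or strata are an exception. They are Mantel-Haenszel estimates over GC bins of 5 percentage points, with Robins-Breslow-Greenland 95% intervals. Intervals and tests cover the counting of peaks, which are not replicates. Median signals were compared with a permutation test of 100000 resamples. Each gene list was compared with 100000 random draws of as many genes, matched in 10 bins of the number of ranked peaks per gene, in a two-sided permutation test. The background for gene lists was the 12263 protein-coding genes with a ranked peak. Of the list names, 4 were matched through a synonym and 1, Dl, was not matched. Lists could share members, so their counts are not independent. Poxm, for example, was counted under motor neuron transcription factors and under muscle and mesoderm.

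Named genes followed a rule set before the data were examined. It took the genes of the 15 strongest peaks, the 10 genes with the most peaks, up to 5 members per fixed list with a peak in the larger list and in both replicates' lists, and Lim3, tup, exex and Sh. Motifs, gene lists, tests and alternatives were also set before the data were examined. The alternatives were the conservative list, the top 50% of the larger list by signal, the list of each replicate alone, other overlap rules, promoter limits of 200 and 1000 bp, random positions, windows of 100 and 500 bp, unmatched backgrounds, and other rules of gene assignment. Chosen after the data were seen were the restriction to the arms, the use of protein-coding genes for assignment, the non-coding exon class, the treatment of scaffolds as 1 class, the removal of the larger list's peaks from the background of the other lists, and the odds ratio interval. A background matched on the full position class, peaks outside promoters, gene lists from promoter peaks alone, 20 matching bins, X scaffolds alone and, for the motif panel, 500 bp windows were further alternatives added after the data were seen. Several splits of the peaks, by replicate, signal and width, were looked at before the split into peaks of 1 replicate alone was kept.

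The tests were tested on simulated data. Of 10 hexamers planted in 5% of 1445 background windows the scan of 2080 hexamers recovered 9, and of 10 planted in 10% it recovered 10, with 0 calls when nothing was planted. With genes drawn by their ranked peaks alone, 2 of 50 runs of the 17 gene lists gave a call. The list of cytoplasmic ribosomal proteins, with 15 of its members added to the drawn genes, was recovered in 50 of 50 runs. No other list was raised, so the power of the test for the other lists was not measured. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.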

Results

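Lim3 is a LIM-homeodomain transcription factor of motor neurons and other neurons, and the data recorded where its eGFP fusion was found on chromatin of whole embryos of 8 to 24 h. The larger list from both libraries held 1500 peaks, of which 1445 lay on the 7 chromosome arms and 55 on scaffolds. The conservative list held 966 peaks, the list of replicate 1 held 881 and that of replicate 2 held 927. The larger list came from 142438 ranked peaks of both libraries, and the conservative list from a separate ranking between the libraries, of 125227 peaks. The lists of the replicates came from 104680 ranked peaks of replicate 1 and 113860 of replicate 2. Most peaks had a fixed width, 330 bp in the lists from both libraries and 300 bp in those of 1 replicate. The median signal was 89.9 in the larger list, 62.3 in replicate 1 and 62.9 in replicate 2, on scales that belong to each list.

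The 15 strongest peaks of the larger list were all present in the lists of both replicates. The first lay in an intron of CG11050 (2L, 6612579 to 6612866, signal 935), 1028 bp downstream of the TSS. Next came the promoter of CG14100 (3L, 19590489 to 19590734, signal 793), that of Ugalt, a transporter of UDP-galactose (X, 2703760 to 2704026, signal 770), and that of mRpL41, a protein of the mitochondrial ribosome (2R, 15217615 to 15217887, signal 755). The fifth (2R, 21703255 to 21703612, signal 750) lay in an intron within the overlapping spans of HmgZ and HmgD, which encode high mobility group proteins. The sixth lay 492 bp upstream of the nearest TSS of ph-p, a Polycomb group gene, and within that gene's span (X, 2137217 to 2137495, signal 718). Promoters of CG7601, mRpL23, Chro, Art3, Tcs5, PNPase and CG18549 followed, with an intron of Adf1, which encodes a transcription factor, in the fifteenth place (2R, 6662942 to 6663187, signal 507). The peak assigned to CG13323 was intergenic, 11923 bp from the TSS of that gene.

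Several genes had clusters of peaks assigned to them by the nearest TSS. The peaks assigned to CG13898, CG7560 and CG43245 lay outside those genes. Ranked peaks of the 10 genes ranged from 10 for CG14434 to 82 for ush, and the counts below were not adjusted for them. CHES-1-like, which encodes a forkhead protein, had 8 peaks between 7696911 and 7709301 on X, 4 of them in the lists of both replicates. The gene ush, which encodes a cofactor of GATA factors, had 6 intronic peaks between 485712 and 522478 on 2L, and 0 of them were in the lists of both replicates. CG13898 and sbb had 6 peaks each, with 3 in both replicates' lists for each gene. Tlk, chinmo, CG7560, Raf, CG43245 and CG14434 had 5 each. The 5 peaks of chinmo, a BTB zinc finger gene that acts in the timing of neuronal fates, lay between 1632727 and 1649879 on 2L, upstream of the gene, and 4 of them were in the lists of both replicates.

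The first comparison asked how far the replicates listed the same regions. Of the 881 peaks of replicate 1, 469 (53.2%, Wilson 95% interval 49.9 to 56.5) overlapped a peak of replicate 2, and of the 927 peaks of replicate 2, 478 (51.6%, 48.3 to 54.8) overlapped a peak of replicate 1. Among the 142438 ranked peaks, 481 met listed peaks of both replicates where 6.21 would meet both by chance, an odds ratio of 321 (Fisher's exact test, with a p too small for the numerical precision). Of the 1445 peaks of the larger list on the arms, 472 were in the lists of both replicates, 241 in that of replicate 1 alone, 328 in that of replicate 2 alone and 404 in neither. Across the 1336 of the 1500 peaks with a value in each replicate, the Spearman correlation of signal was 0.453 and the Pearson correlation of log10 signal was 0.450. Peaks are not independent replicates, and the Spearman value was 0.631 in the conservative list and 0.161 over all ranked peaks.

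Promoters held 670 of the 1445 arm peaks (46.4%, Wilson 95% interval 43.8 to 48.9), against 13.4% of the 137764 ranked background peaks. The odds ratio was 5.61 (5.05 to 6.23, adjusted p = 3.88e-199, Fisher's exact test). Coding sequence held 1.31% of peaks against 19.9%, 3' UTRs 0.900% against 2.33%, and intergenic regions 13.8% against 24.8%, with adjusted p of 6.56e-107, 0.000164 and 3.42e-24 by Fisher's exact test. Introns held 518 peaks (35.8% against 37.9%), a difference that did not pass (adjusted p = 0.114, Fisher's exact test). The intron share lay below background and passed in 5 of 7 alternatives, among them the conservative list (34.4% against 37.9%) and promoters of 1000 bp (28.0% against 35.0%). It turned above its background, at 43.9% against 39.6%, when promoters were limited to 200 bp. Random positions on the same arms fell in promoters at 13.6%, near the 13.4% of the ranked background peaks. That background thus resembled random positions in its promoter share. With no control library analysed, the promoter share cannot be tied to the fusion alone.

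**Figure D1:**
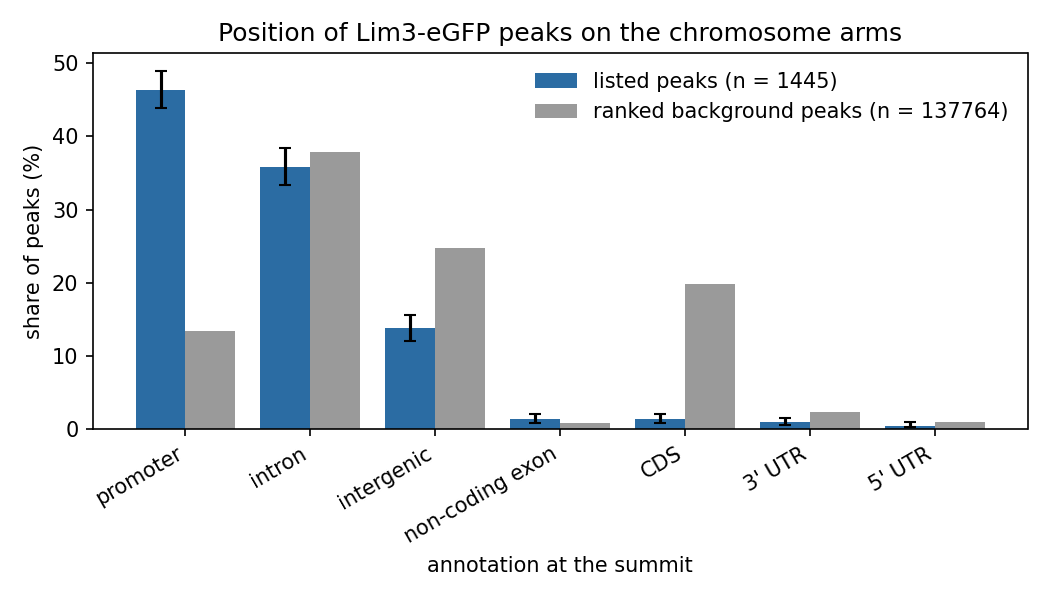
Share of peaks (%) in each annotation class at the summit, for the 1445 arm peaks of the larger list (blue, bars with Wilson 95% intervals) and 137764 ranked background peaks (grey). Promoters took 46.4% of listed peaks against 13.4%, and coding sequence 1.31% against 19.9%.

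By chromosome, arm 3R held fewer listed peaks than background peaks (20.1% against 25.2%, adjusted p = 3.68e-05, Fisher's exact test), a call that was lost without replicate 1 (22.2% against 25.2%, adjusted p = 0.0590). Scaffolds held more (3.67% against 2.19%, adjusted p = 0.00146, Fisher's exact test). All listed scaffold peaks lay on scaffolds assigned to X. This followed from the deposited lists, which left out every peak past the IDR limit on other scaffolds, 59 for the larger list. With the other scaffolds left out, an alternative chosen after the data were seen, the scaffold share was 3.67% against 0.569% (odds ratio 6.65, adjusted p = 4.78e-25, Fisher's exact test). Scaffold peaks numbered 108 in the list of replicate 1 and 1 in that of replicate 2. In the conservative list their share was 1.24%, below its background, and without replicate 1 it was 0.108%. X, 2L, 2R, 3L, 4 and Y did not pass.

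TAATTA, the core bound by LIM-homeodomain and many other homeodomain proteins, occurred in 291 of the 1445 windows around summits (20.1%, Wilson 95% interval 18.2 to 22.3). Matched background windows had it in 16.7%, an odds ratio of 1.26 (1.09 to 1.45, p = 0.00196, adjusted p = 0.0118 over the panel, Fisher's exact test). AATATT, a rearrangement of the same letters, was as high at 1.29 (adjusted p = 0.00125, Fisher's exact test), and ATTAAT and TTATAA had odds ratios of 1.19 and 1.20. The TAATTA difference held in the list of replicate 2 (23.5% against 17.1%) and not in that of replicate 1, where the share lay below background (16.7% against 18.6%). It was larger in 100 bp windows, where 174 of 1445 held the word against 8.35% of background (odds ratio interval 1.26 to 1.80, adjusted p = 9.91e-05, Fisher's exact test), and there TTATAA, AATATT and ATTAAT passed as well, with odds ratios of 1.61, 1.46 and 1.304. It did not pass in the conservative list (18.8% against 18.3%), in the top 50% of peaks by signal (19.6% against 20.3%), in 500 bp windows (31.6% against 31.8%) or outside promoters (18.97% against 16.4%, an alternative chosen after the data were seen).

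Within the rest of the panel, GAGAG, the site of GAGA factor, was higher in peaks (23.9% against 19.4%, odds ratio 1.31, adjusted p = 0.00125, Fisher's exact test). TAATTG was lower (19.1% against 22.2%, odds ratio 0.826, adjusted p = 0.0383, Fisher's exact test). The other motifs of the panel did not pass, among them the Zelda site CAGGTAG, the DRE TATCGATA and the M1BP core GTCACACT. The DRE and the M1BP core passed against an unmatched background (odds ratios 4.70 and 2.56) and in 500 bp windows (4.43% against 2.99% and 3.46% against 2.26%), the latter chosen for the panel after the data were seen. The E-box CAGCTG missed narrowly (8.79% against 6.90%, adjusted p = 0.0501, Fisher's exact test), and it passed in the conservative list (odds ratio 1.48) and the top 50% by signal (1.71) but not in the list of either replicate. In 100 bp windows CAGCTG lay below background (3.04% against 3.28%) and did not pass, and in 500 bp windows it passed (27.1% against 18.6%). The GATA core TGATAA passed in the list of replicate 2 (19.3% against 15.4%, adjusted p = 0.0138, Fisher's exact test) and not in that of replicate 1. GAGAG was strongest in 500 bp windows (56.7% against 43.7%, odds ratio 1.69), lay below background in 100 bp windows (9.55% of peaks) and did not pass with an unmatched background (23.9% against 23.0%). The TAATTG call was lost in the list of each replicate, in 100 bp windows and, in alternatives chosen after the data were seen, outside promoters and with a background matched on the full position class, and TAATTG lay above an unmatched background. Peaks with TAATTA had a median signal of 89.1 and those without it 91.0, and the difference of −1.94 did not pass a permutation test (p = 0.629).

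The strongest words came from the scan of 2080 hexamers, of which 136 were higher and 95 lower in peaks after adjustment. ACAGTG led, in 317 of 1445 windows (21.9%) against 8.83% of matched background windows, an odds ratio of 2.90 (adjusted p = 3.77e-37, Fisher's exact test). In order of p, the words CAGTGG, ACTGTG, ACTGTA and CTGTGC came next, with odds ratios from 2.02 to 2.20. ACCCCC, further down that order, had an odds ratio of 2.39. ACAGTG was at 24.5% of windows in the list of replicate 1, 23.5% in that of replicate 2 and 24.4% in the conservative list, against 8.93%, 8.27% and 8.85% of their backgrounds. The word was absent from the windows of all 15 strongest peaks. The number of hexamers past the threshold fell from 231 to 79 with replicate 1 alone and to 102 in the top 50% of peaks by signal.

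**Figure D2:**
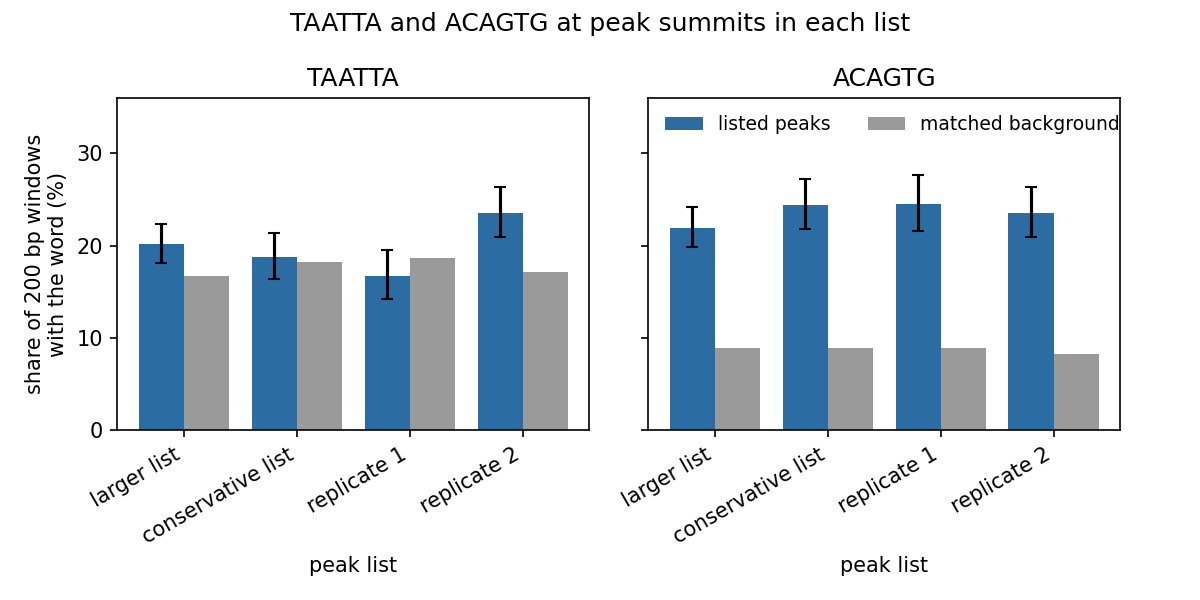
Share (%) of 200 bp windows holding TAATTA (left) or ACAGTG (right) in each peak list (blue, bars with Wilson 95% intervals) and in its matched background (grey). ACAGTG stood at 21.9% or more in the 4 lists, whereas TAATTA was at 16.7% in replicate 1 and 23.5% in replicate 2.

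The last comparison asked which fixed groups of genes lay near the peaks. The 1445 arm peaks fell to 1149 of 12263 genes. Genes of cytoplasmic ribosomal proteins were the group that passed, with 15 of 81 having a peak where 5.58 were drawn on average (adjusted p = 0.0112, permutation test). Of these 15 genes, 2 had a peak in the lists of both replicates. They were RpL32 (3R, 30046150 to 30046479, signal 160) and RpL23A (3L, 1668560 to 1668889, signal 111), each at the promoter. Taken by themselves, the peaks of both replicates gave 2 genes where 2.17 were drawn on average. The call was kept with gene bodies extended by 2 kb (21 genes against 8.40) and with TSSs within 5 kb (15 against 4.50), and also with promoter peaks alone (15 against 3.77) and 20 matching bins (15 against 5.57), both chosen after the data were seen. It was lost with the conservative list (10 against 3.86), the top 50% by signal (6 against 3.19), the list of replicate 1 (5 against 3.32), that of replicate 2 (5 against 3.75) and unmatched draws (15 against 7.59).

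Motor neuron transcription factors had peaks at 6 of 13 genes (Poxm, Lim3, exex, grn, Oli and tup) where 2.48 were drawn on average. The difference did not pass adjustment (p = 0.0450, adjusted p = 0.294, permutation test), although it did with unmatched draws (adjusted p = 0.0109, Fisher's exact test), as did epidermis and trachea genes (7 of 22, adjusted p = 0.0256). Of the 6 genes, 4 had such a peak in the list of replicate 2 and 0 in that of replicate 1. Taken by itself, the list of replicate 2 gave 4 genes against 1.54 drawn, and that of replicate 1 gave 1 against 1.48. Lim3 itself had a peak in its intron (2L, 19087226 to 19087555, signal 92.5) and one 252 bp upstream of its TSS (2L, 19108514 to 19108843, signal 63.2). The peak upstream of the TSS was in neither replicate's list nor in the conservative list. Its rank was 4778 in replicate 1 and 2811 in replicate 2. The peak of exex, which encodes a homeodomain protein of motor neurons, lay 7062 bp downstream (3L, 7955083 to 7955412, signal 79.5). The peak of tup, an Islet gene, lay 30906 bp upstream (2L, 18912002 to 18912331, signal 57.1). It was not in the conservative list, and its rank in replicate 1 was 42130. Its window held TAATTA, and the windows of the listed peaks at the other genes of the 6 did not. The potassium channel gene Sh had 0 listed peaks, and its strongest ranked peak stood at place 8544 of 142438.

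The other lists did not pass adjustment with matched draws. Neuropeptide genes had a peak at 0 of 21, neuronal identity transcription factors at 2 of 35 (scrt and eg), and axon guidance and cell adhesion genes at 9 of 71, where 2.03, 6.57 and 13.6 were drawn on average. Axon guidance and cell adhesion genes had fewer peaks than the central 95% of draws in 4 alternatives, the lowest adjusted p being 0.0510 with gene bodies extended by 2 kb (11 genes against 21.4, permutation test). Genes of neurotransmitter synthesis and transport had 1 of 14 (Ddc) and ion channels 4 of 25. The list of synaptic vesicle and active zone genes, which also held elav, had 3 of 18, with elav among these 3. Neuroblast temporal and progenitor genes had 3 of 19, the LIM homeodomain genes and cofactors 3 of 10, and the Hox genes and cofactors 2 of 9. Notch pathway genes had 4 of 16, and glial genes 4 of 14. Among the remaining groups, muscle and mesoderm genes had 7 of 31, and gut, fat body and blood cell genes 4 of 17. Epidermis and trachea genes had 7 of 22, and histone and heat shock genes 2 of 25. The adjusted p of these lists ranged from 0.294 to 1 (permutation test).

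Members of these lists with a peak in the larger list and in the lists of both replicates included genes of many tissues. Among neural genes they were numb, an inhibitor of Notch (promoter, 2L, 9449522 to 9449687, signal 237), brat (intron, signal 216), neur, a ubiquitin ligase of the Notch pathway (intron, signal 165), and edl (intron, signal 277). The promoter of elav, which encodes a neuronal RNA-binding protein (X, 523322 to 523651, signal 224), and that of moody, a receptor gene of the glial barrier (X, 2050213 to 2050330, signal 175), also had peaks. The summit at elav lay within the span of the gene arg, and that at moody within the span of CG4313. Peaks lay in introns of the adhesion gene Fas3 (signal 136) and the potassium channel gene Irk1 (signal 125), and 904 bp upstream of the calcium channel gene Ca-alpha1T (signal 126). Ribosomal proteins aside, the members from the remaining lists were bowl (promoter, signal 158) and the heat shock genes Hsp27 (promoter, signal 280) and Hsp83 (intron, signal 94.97). The last was crq, a scavenger receptor gene of blood cells (signal 133), whose peak lay within the span of the neighbouring gene ex.

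**Figure D3:**
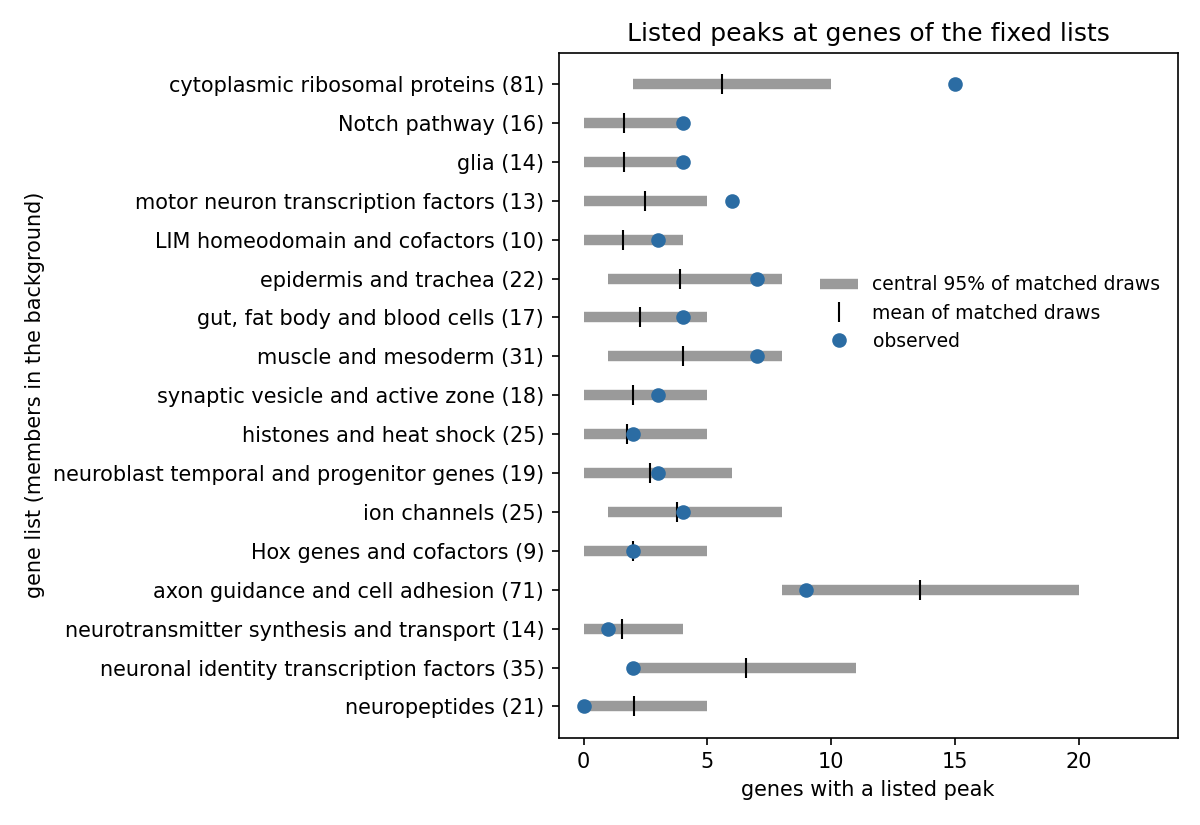
Number of genes with a listed peak in each of the 17 fixed lists (blue points), with the mean (black ticks) and the central 95% (grey bars) of 100000 matched draws; the number of members in the background stands after each name. Cytoplasmic ribosomal proteins, with 15 genes, passed adjustment, and motor neuron transcription factors, with 6 genes, did not.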

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

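The alternatives with a background matched on the full position class, peaks outside promoters, 20 matching bins, promoter peaks alone, X scaffolds alone and, for the motif panel, 500 bp windows were chosen after the data were seen. The promoter, CDS and intergenic differences kept their direction and side of the threshold in the 7 alternatives run for each, and ACAGTG, CAGTGG, ACTGTG, ACTGTA and CTGTGC did so in the 6 run for each. The stricter IDR limit of 0.01 moved nothing, since the 1500 listed peaks already met it. The cause of the changes below was not tested. The Spearman correlation of the replicates was 0.631 in the conservative list and 0.161 over all ranked peaks. For TAATTA the share of peaks was 18.8% in the conservative list, 19.6% (below background) in the top 50% by signal, 31.6% (below) in 500 bp windows and 18.97% outside promoters, and it ranged from 16.7% (below, without replicate 2) to 23.5% with 1 replicate left out. The median signal with TAATTA minus that without was 4.68 in the conservative list and ranged from −1.64 to 4.29 with 1 replicate left out. Of the chromosome classes, 1 passed in the top 50% by signal and 2 to 3 with 1 replicate left out. The motif panel gave 14 calls unmatched, 8 in 500 bp windows, 7 matched on the full position class and 2 to 5 with 1 replicate left out. The hexamer scan gave 102 calls in the top 50% by signal, 129 outside promoters and 79 to 144 with 1 replicate left out. Gene lists gave 0 calls in the conservative list, the top 50% by signal and each replicate alone, and 2 with unmatched draws. Reversed relative to background were the intron share with promoters of 200 bp (43.9%), the scaffold share in the conservative list (1.24%) and without replicate 1 (0.108%, against 12.3%, not reversed, without replicate 2), GAGAG in 100 bp windows (9.55%), TAATTG against unmatched windows (19.1%) and motor neuron transcription factors without replicate 2 (1 gene, against 4, not reversed, without replicate 1). Read depth is unknown, so how far depth limits the lists cannot be judged from these files.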

Other observations

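The tests of TAATTA within GC bins, of the composition controls between replicates, of TAATTA by the number of controls and without high-ranked peaks, of ACAGTG against the full position class and by distance band, of octamers, of hexamers between replicates, and of the scaffold peaks were chosen after the results were seen, as were the words ACAGTG and CTTATC and the split of peaks by replicate.

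Peaks listed for replicate 2 alone held GATA-type words more often than those of replicate 1 alone. CTTATC, which reads GATAAG on the other strand, occurred in 101 of 449 windows of replicate 2 alone (22.5%) and in 25 of 305 of replicate 1 alone (8.20%), an odds ratio of 3.25 (adjusted p = 0.000215 over 2080 hexamers, Fisher's exact test). Of these hexamers 3 passed between the replicates, CTTATC, TAATTA and AATTAA, which overlaps TAATTA. TGATAA, the GATA core of the panel, was at 23.6% against 14.4% (adjusted p = 0.00561 over 8 words, Fisher's exact test). In peaks of both replicates CTTATC was at 8.18%, against 9.36% of their matched background.

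At octamer length the words around ACAGTG led again. CACAGTGG occurred in 6.23% of windows against 1.21% of matched background windows, and CACTGTGC in 6.30% against 1.29%. Of 18404 octamers, 102 were higher after adjustment. Counted in steps of 25 bp, ACAGTG copies were most frequent 75 to 100 bp from the summit, at 11.5 copies per 100 peaks against 2.21 in the background. Within 25 bp of the summit the values were 2.56 and 2.19. The strongest region past the IDR limit that was missing from the larger list lay near cbt (2L, 480959 to 481239, signal 908).

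TAATTA occurred in 127 of 449 windows of replicate 2 alone (28.3%) and in 42 of 305 of replicate 1 alone (13.8%), an odds ratio of 2.47 (1.67 to 3.60, adjusted p = 0.00219 over 2080 hexamers, Fisher's exact test). Base composition alone was argued against by the odds ratio within GC bins, 2.65 (1.77 to 3.98). An AT-rich neighbourhood was argued against as the whole cause, since the odds ratio was 2.57 (1.69 to 3.91) within strata of GC and of the number of ATTAAT, TTATAA and AATATT words held, and that of windows with any of these controls was 1.05 (0.781 to 1.40), although ATTAAT by itself was at 1.57 (1.05 to 2.36) within GC bins and the central test set beforehand separated nothing, because TAATTA (2.36) and the controls (1.94, 1.82 and 1.65) were all centred on the summits. On near-misses at the threshold the tests differed. With peaks ranked in the top 5% of the other replicate left out, TAATTA was at 30.6% (88 of 288) against 7.96% (9 of 113). The odds ratio was 5.08 (2.39 to 9.87, p = 5.46e-07, Fisher's exact test). That argues against near-misses as the whole cause, but the 2 sets were unlike. Before this step, the median rank percentile in the other replicate was 72.3 for peaks of replicate 2 alone and 97.8 for those of replicate 1 alone. Promoters held 34.5% and 44.6% of them, a difference that was not matched. The test set beforehand compared median rank percentiles in replicate 1, for peaks of replicate 2 alone with and without TAATTA. These were 71.2 and 72.6 (−1.33, p = 0.963, permutation test), and equal medians were the outcome predicted for near-misses. A lack of difference cannot establish near-misses, so they were not excluded. The design has 1 group, so no biological explanation was tested, and a difference between the embryo collections or libraries stays open.

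ACAGTG stayed higher against a background matched on the full position class (odds ratio 3.15) and outside promoters (3.53), which argues against position class or promoter sequence as the whole cause. A general enrichment of the neighbourhood was tested with the share of copies in 500 bp windows that lay within 50 bp of the summit. That share was lower in peaks than in background (odds ratio 0.674, p = 0.000836, Fisher's exact test), as such a neighbourhood would allow. The copies themselves were not fewer there. They numbered 2.56 per 100 peaks against 2.19 in background within 25 bp, and 4.78 against 2.46 from 25 to 50 bp. The band from 50 to 150 bp, chosen after the distances were seen, held 66.2% of copies against 42.1% (odds ratio 2.70, 2.25 to 3.22), which an even spread does not give. The word was picked from a scan of these same peaks, so these tests are not independent of it. A candidate explanation is a sequence element beside the summit, as a hypothesis, and no biological explanation was tested.

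Replicate 1 listed 108 scaffold peaks on 84 scaffolds, all assigned to X, and replicate 2 listed 1. Near-misses at the threshold were argued against, since scaffold peaks had a ranked peak in replicate 2 less often than arm peaks of replicate 1 alone (odds ratio 0.0690, p = 2.65e-26, Fisher's exact test). Removal of regions by the authors was argued against as the whole cause, since replicate 2's ranking held 3 scaffold peaks past the IDR limit among 925 (p = 5.56e-11, Fisher's exact test), although both lists lacked every such peak on other scaffolds. A difference between the libraries in repeated sequence stays open, and no biological explanation was tested.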
